A study of Mus musculus with 4 samples.

How the data were processed

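RNA was measured by sequencing in mouse embryonic fibroblasts (strain background C57BL/6) on day 5 of reprogramming with SeVdp(KOSMaB), a Sendai virus vector that carries Klf4, Pou5f1 (Oct4), Sox2 and Myc. Per the labels' protocols, cells were selected with 2 µg/mL blasticidin S, RNA was extracted with ISOGEN, and libraries were made with poly(A) selection and a directional (stranded) kit. Cells expressed Osr2 or, as the control, Kusabira Orange, and were grown with or without 10 µM SB431542, an inhibitor of the TGF-β type I receptor kinases. Each of the 4 groups has 1 library.

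Per the series design text, the authors sequenced on a NovaSeq instrument, mapped the reads to the mouse genome GRCm38.p6 with STAR 2.7.3a at default parameters, counted reads per gene with featureCounts 2.0.0, and converted the counts to TPM. The values in the deposited tables are therefore TPM, as the authors made them. The design text names an Ensembl annotation, release 75, while 24973 of the 26949 gene symbols (92.7%) are RefSeq symbols of this genome build, so gene positions are given from the RefSeq annotation of GRCm38.p6. The TPM values of the listed genes add up to 346607, 453128, 270515 and 96191 in the control library without SB431542, the control library with it, the Osr2 library without it and the Osr2 library with it. They are thus relative to totals that the listed genes do not hold, and these totals differ between libraries.

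A second table with 4 columns, whose names match no sample of the series, was not used here. Of 27304 entries in the table used, 26 whose names had been turned into dates, and which held 26 cells that are not numbers, were left out, as were 469 entries that share 140 symbols. All 984 members of the gene lists were looked up by symbol, then by the annotation's synonyms or, for mitochondrial genes, the names in the table, and 983 have an entry.

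Because TPM of a gene steps by whole reads over its length, the whole read numbers could be recovered from the 4 columns together. For 18882 of the 18883 entries with a value above 0, the 4 values were whole reads at 1 gene length, within 0.001 of a whole number. The value of 1 read was set from 110 small RNA genes with 1 RefSeq locus, and 344 of 460 such genes had a recovered length equal to the RefSeq length. On simulated data, reads were recovered up to a factor common to the 4 libraries in 100% of 395 entries and exactly in 93.4%, so totals are lower limits. The recovered totals were 17997030, 13146461, 14210523 and 1631971 reads in the same order of libraries. A gene with 0 reads could be present at up to 3 reads, or 0.167, 0.228, 0.211 and 1.84 reads per 10⁶ reads. These limits and the exact 95% intervals on ratios of reads cover counting error only. For single genes no such limit is used in the Osr2 library with SB431542, where 0 reads were more frequent than counting error gives. For some list medians, members at 0 reads were also set to 3 reads. This shows what the zeros change and is no limit.

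Differences are of log2(TPM + 1). A gene counted as measured with at least 1 TPM in at least 1 of the 4 libraries (13509 genes), and as higher or lower with a difference of at least 1 in size. With 1 library per group there is no estimate of spread, so genes are counted by size and no test of single genes was made. The 4 comparisons are Osr2 against control without and with SB431542, and SB431542 against none in control and in Osr2 cells, with the difference between the last pair as a further value. Pearson and Spearman correlations between comparisons are across genes, which are not independent replicates.

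The libraries also differ by a shift of all genes, so differences are given relative to the median gene. For this each library was divided by its median ratio to the control library without SB431542 over 7868 genes of mean TPM of at least 5. For each comparison the numbers of genes on TPM as deposited stand beside the relative ones. No entry had fewer reads in an untreated column than in its treated column, so the treated reads may lie within the untreated ones. They are called shared reads below, though only numbers of reads are known. Values are therefore also given after read subtraction. For it the treated reads are taken from the untreated column, TPM is rebuilt and the libraries are again set to the median gene. Folds of single genes are ratios of reads relative to the median gene, without the pseudocount of the log2 differences. At low TPM they are thus larger in size than the log2 difference on the same values gives. Ratios for SB431542 against none use the untreated reads left after this subtraction. The relative values and the read subtraction were chosen after seeing the data.

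The comparisons, the size rule, 40 gene lists with 5 primary ones (TGF-β/Smad3 targets, mesenchymal and EMT genes, epithelial genes, the pluripotency network, canonical Wnt targets), the rule for named genes and 10 alternatives were fixed before the data were examined. A list's median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and was said to stand apart below the 2.5th or above the 97.5th percentile. This describes these libraries and is no p-value. 1 list, of Y-linked genes with Xist, had too few measured members to be placed, which leaves 39.

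The named genes are Osr2, the vector's 4 factors, the 5 genes with the largest difference in each direction among genes of at least 5 TPM in either library of the comparison, and the 4 members of a list with the largest differences. The rule was applied to TPM as deposited and, after the shift was seen, to the relative values as well. A gene named in 1 comparison may be given in others.

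The steps were tested on simulated data with 200 genes set 4-fold apart in the recovered libraries. On relative values 100% of the higher and 96% of the lower genes were found for Osr2 against control without SB431542, 100% and 98% with SB431542, and 98% and 98% for SB431542 in Osr2 cells. For SB431542 in control cells 0% and 0% were found as the columns stand, and 100% and 100% after read subtraction. Of unchanged genes 0.143%, 1.03%, 0.965% and 0.0261% passed the size rule, for the comparisons in the order just given. The genes scored were the 7868 of mean TPM of at least 5, and the simulated reads varied by counting error alone. These shares are thus no rate of false calls among the 13509 measured genes. Of lists shifted by 1 (log2), 98% lay outside the percentiles, against 4.5% of lists without a shift.

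The alternatives were pseudocounts of 0.1 and 5, a filter of 5 TPM and none, median-of-ratios scaling, rescaling without mitochondrial genes and the 20 genes of highest mean TPM, size rules of 1.5-fold and 4-fold, the mean in place of a list's median, and list members of at least 5 TPM. The relative values and the read subtraction were run in the same way as 2 added alternatives, with 2000 random lists for each. GC content and transcript length were taken from the longest transcripts of GENCODE M21 on the same genome build. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.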

Results

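Gene expression was measured by poly(A) RNA sequencing on day 5 of reprogramming in mouse embryonic fibroblasts that expressed Osr2, a zinc-finger transcription factor, or Kusabira Orange, a fluorescent protein that served as the control. Each kind of cell was grown without and with SB431542, so the data hold 4 groups of 1 library each, and the differences have no replicate check. The recovered depth was 17997030 reads in control cells without SB431542, 13146461 in control cells with it, 14210523 in Osr2 cells without it and 1631971 in Osr2 cells with it. At least 1 TPM was reached by 12388, 13033, 11247 and 6259 table entries in these libraries.

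The Osr2 library with SB431542 stood apart in its make-up. Genes encoded by the mitochondrial genome held 15.3% of its reads, against 1.77% and 0.705% in the control libraries without and with SB431542 and 2.46% in the other Osr2 library. The 20 entries with most reads held 21.2% of its reads, against 6.36%, 5.92% and 16.4%. Of 9144 genes for which the control library with SB431542, taken down to this depth, would give at least 20 reads, 183 had 0 reads here, against 0 when that control library was thinned at random. Genes at 0 reads in this library are therefore given without a bound on the ratio, and the counting intervals of genes with few reads here leave out this loss.

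Within each kind of cell, no entry had fewer reads without SB431542 than with it. In control cells 15306 of 18150 entries had more reads without the inhibitor and 2844 had equal numbers, and in Osr2 cells 16502 of 16754 had more and 252 had equal numbers. The treated column amounted to 73.0% of the untreated reads in control cells and 11.5% in Osr2 cells. Between the 2 kinds of cell, each of the 4 pairings had at least 188 entries with more reads in either column. Comparisons of SB431542 with none, and comparisons that use an untreated column, are therefore also given after subtraction of the treated reads.

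**Figure D1:**
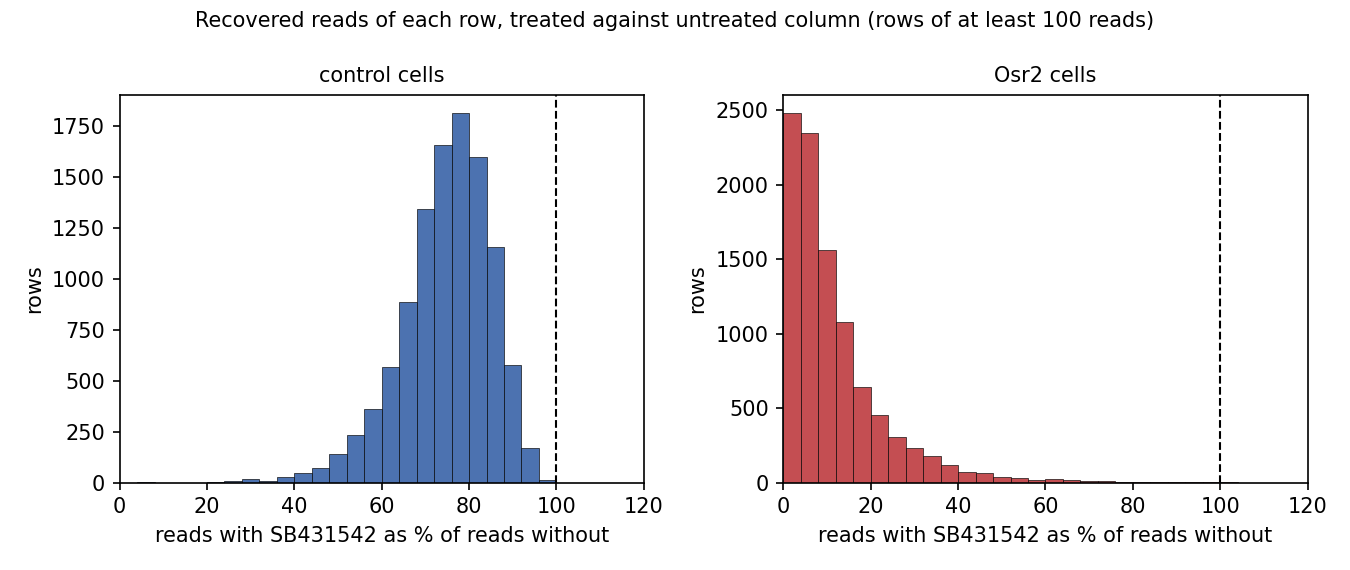
Reads with SB431542 as a percent of reads without it (x axis) for each entry of at least 100 reads in the untreated column, as numbers of entries (y axis), in control cells (left) and Osr2 cells (right). The dashed line marks equal reads, and the medians are 76.0% in control cells and 8.09% in Osr2 cells.

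The median gene was shifted between libraries by −0.80 (log2) for Osr2 against control without SB431542, −3.51 with SB431542, 0.46 for SB431542 in control cells and −2.25 for SB431542 in Osr2 cells. After read subtraction these shifts were 0.87, −3.46, 1.30 and −3.03. All log2 differences below are relative to the median gene unless another scale is named.

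Osr2 itself (chromosome 15, 35296098 to 35303305, GRCm38.p6) matched the labels. It stood at 0.890 TPM (47 reads) in control cells and 59.1 TPM (3002 reads) in Osr2 cells without SB431542, and at 0.764 TPM (22 reads) and 13.7 TPM (311 reads) with it. Relative to the median gene this was 116-fold higher without SB431542 (95% counting interval 86.6 to 158) and 205-fold higher with it (133 to 332), and without SB431542 the log2 difference was 5.78, or 4.71 after read subtraction. Its paralog Osr1 differed by 0.38 and −0.03 in the same comparisons, with −0.38 and −2.90 on TPM as deposited. The 4 factors of the vector, whose reads may come from the vector or from the endogenous genes, were abundant in all 4 libraries, with Sox2 at 2160, 3081, 1024 and 446 TPM and Klf4 at 1322, 1687, 711 and 362 TPM.

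**Figure D2:**
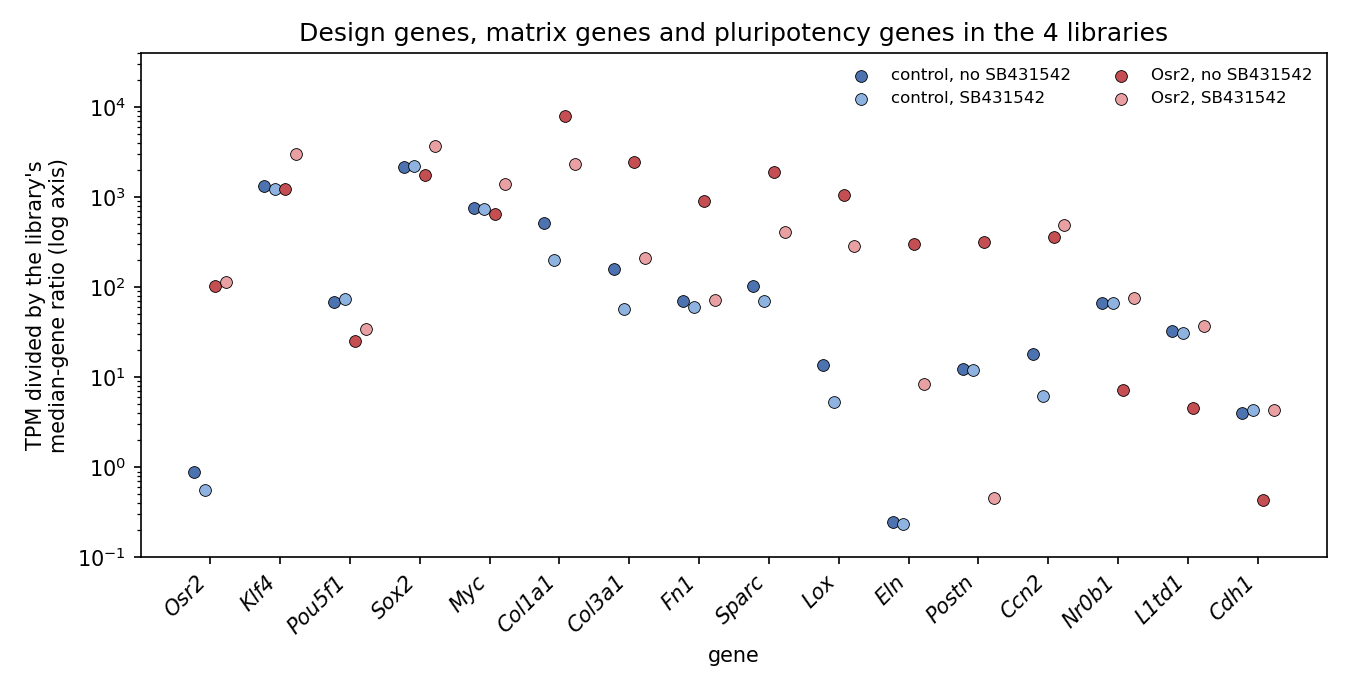
TPM divided by the library's median-gene ratio (y axis, log scale) for 16 genes (x axis), with 1 point for each of the 4 libraries and no point where a library had 0 reads. Osr2 separates the Osr2 from the control libraries, the matrix genes from Col1a1 to Postn are highest in the Osr2 library without SB431542, and Nr0b1, L1td1 and Cdh1 are lowest in that library.

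The first comparison asks what differed when Osr2 was expressed during reprogramming without the inhibitor. Genes of the extracellular matrix were higher with Osr2. Elastin (Eln, chromosome 5, 134702595 to 134747368) was 1231-fold higher (counting interval 857 to 1839), at 0.246 against 173.8 TPM. Lox (chromosome 18, 52516060 to 52529867), the enzyme that crosslinks collagen and elastin, was 76.7-fold higher (71.9 to 81.8). Col1a1 (chromosome 11, 94936224 to 94953042) and Col3a1 (chromosome 1, 45311538 to 45349706), the main fibrillar collagens of connective tissue, stood at 522 and 158 TPM in control cells and at 4616 and 1415 TPM in Osr2 cells, or 15.4-fold (15.2 to 15.5) and 15.6-fold (15.4 to 15.8) higher. In log2, Eln, Lox, Col1a1 and Col3a1 differed by 7.93, 6.16, 3.94 and 3.95, and after read subtraction by 7.23, 4.71, 2.45 and 2.45. The medians of the pluripotency, epithelial and cell-cycle lists were below 0.

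By group, 39 of 40 matrix genes were higher and 0 lower, with a median of 3.63, above all 10000 random lists. Mfap4, a microfibril protein, differed by 6.25 and Aspn by 5.85. Of the 37 TGF-β/Smad3 target genes, 34 were higher, 0 lower and 3 neither, with a median of 2.43, also above all random lists. Their examples beyond Lox include Postn, a matricellular protein, at 4.58, and Timp3, an inhibitor of matrix proteases, at 4.89. Of the 25 mesenchymal and EMT genes, 20 were higher, 0 lower and 5 neither (median 1.92), among them Sparc (4.18), the proteases Mmp3 (4.11) and Mmp2 (3.79), and fibronectin Fn1 (3.64). Contractile genes of myofibroblasts and smooth muscle were higher in 16 of 17 (median 2.43, 1.60 after read subtraction), with Acta2, smooth muscle actin, at 4.35 and Myl9 at 4.05. Of 23 embryonic fibroblast markers, 19 were higher and 0 lower (median 2.62). These lists share members, so their medians are not independent of each other. Col1a1, Col1a2, Col3a1, Postn and Lox are among the genes in both the matrix and the TGF-β target list. Acta2, Tagln and Cnn1 are among those in both the TGF-β target and the contractile list.

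Lists of secreted signals and their receptors had medians above 0 as well. Of 34 TGF-β ligands, receptors and Smads, 17 were higher, 2 lower and 15 neither (median 1.11, 0.40 as deposited and 0.62 after read subtraction), with Ltbp2 at 3.50, Acvrl1 at 3.32 and Tgfbr2 at 2.81, and Acvr2b at −2.01. Of 19 BMP pathway and Id genes, 11 were higher and 0 lower (median 1.29), against 7 higher as deposited and 4 after read subtraction (median 0.74), with Bmp4 at 2.94. Of 32 Wnt ligands, receptors and inhibitors, 16 were higher and 2 lower (median 1.02), against 8 and 5 as deposited (median 0.33) and 12 and 4 after read subtraction (median 0.48), with Dkk2, a secreted Wnt inhibitor, at 4.95 and Wnt2 at 3.18. Canonical Wnt targets were higher in 11, lower in 3 and neither in 12 of 26, with Lgr5, a receptor for R-spondins, at 4.74 and Ccn4 at 4.30. The Wnt targets' median was 0.45, at the 98.4th percentile, but −0.14 on TPM as deposited and 0.31, at percentile 94.1, after read subtraction, and on TPM as deposited it no longer stood apart with no filter. Igfbp3, which binds insulin-like growth factors, was 138-fold higher in reads (118 to 163). Its log2 difference, with the pseudocount, was 6.73, against 5.77 after read subtraction.

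Among stress and early response genes, 11 of 24 targets of the unfolded protein response and ATF4 were higher and 1 lower (median 0.86), against 6 and 5 as deposited (median 0.08), with Nupr1 at 3.55, Trib3 at 3.36 and Cth at −2.87. Of 17 immediate early genes, 11 were higher and 0 lower (median 1.26), but after read subtraction 5 were higher and 1 lower with a median of 0.37 inside the percentiles (percentile 95.2), with Fos at 3.44 and Fosb at 3.17. Macrophage and leukocyte markers were higher in 12 of 15 and lower in 0 (median 1.46), against 6 higher as deposited, with the complement genes C1qa at 3.64 and C1qb at 3.12. Interferon-stimulated genes had a median of 0.38 (percentile 97.65), but of −0.37 on TPM as deposited and −0.26 after read subtraction, both inside the percentiles.

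Pluripotency genes were lower with Osr2 in 11, higher in 2 and neither in 11 of 24, with a median of −0.92, below all random lists. Nr0b1 (Dax1, chromosome X, 86191775 to 86195947), a nuclear receptor of pluripotent cells, stood at 67.3 TPM in control and 4.14 TPM in Osr2 cells and differed by −3.06, but its 105 reads in Osr2 cells equalled those with SB431542, so after read subtraction it had 0 reads there and differed by −5.26. Tdh, the threonine dehydrogenase of mouse pluripotent cells, differed by −2.87, Sall4 by −2.64 and L1td1 by −2.58, while Klf2 differed by 3.03, with −2.12 for Tdh, −3.71 for L1td1 and 1.37 for Klf2 after read subtraction. Of the vector's factors, Pou5f1 differed by −1.39, Sox2 by −0.28, Myc by −0.21 and Klf4 by −0.09. Epithelial genes were lower in 7, higher in 2 and neither in 10 of 19 (median −0.80, percentile 0.14), while on TPM as deposited the median no longer stood apart with a pseudocount of 5, a filter of 5 TPM or the mean over members. E-cadherin (Cdh1, chromosome 8, 106603350 to 106670247) differed by −1.81 and the tight junction gene Cldn3 by −2.06, while P-cadherin (Cdh3) differed by 4.04 and F11r by 1.56.

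Genes of proliferation were lower too. Of 38 cell-cycle genes, 26 were lower and 0 higher (median −1.15), with Uhrf1, which maintains DNA methylation at replication, at −2.18, Mcm5, of the replicative helicase, at −1.85, and Rrm2 at −1.73. Of 21 replication-dependent histone genes, 17 were lower and 0 higher (median −1.76), with H4c1 at −2.65. Of 6 trophoblast genes, 4 were lower and 1 higher (median −1.77), with Peg10 at −3.17 as the lowest member. Neural genes were lower in 4 and higher in 0 of 7 (median −1.15), with Sox1 at −2.91. Inflammatory cytokines were lower in 4 and higher in 3 of 17 (median −0.73), but lower in 10 and higher in 3 both as deposited (percentile 3.13, inside the percentiles) and after read subtraction, with Cxcl5 at −2.09 and Cxcl12 at 3.23. Prkcb (chromosome 7, 122289104 to 122634402), a protein kinase C, was 51.8-fold lower in reads (41.0 to 66.4). Its log2 difference, with the pseudocount, was −4.82, against −3.69 after read subtraction.

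In all, 2236 of 13509 genes were higher and 1540 lower, against 1051 higher and 4132 lower on TPM as deposited and 1936 and 1454 after read subtraction. Of 39 lists 23 stood apart, 17 of them on all 3 scales, while 9 medians had the opposite sign as deposited and 4 after read subtraction. The medians of the matrix, TGF-β target and mesenchymal lists after subtraction were 2.705, 1.75 and 1.52, and those of the epithelial and pluripotency lists −0.68 and −1.13. The 8 measured mitochondrially encoded genes had a median of 0.66, but of −0.14 on TPM as deposited and −3.23 after subtraction.

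The second comparison asks the same of cells grown with SB431542. The pentraxin Ptx3 (chromosome 3, 66219887 to 66225806), a secreted pattern recognition protein, was 112-fold higher with Osr2 (108 to 116), at 1420 against 145 TPM. Egr4 (chromosome 6, 85511121 to 85513589), an early response transcription factor, was 309.8-fold higher (188 to 548). Lox was 53.3-fold higher (46.6 to 61.1), and Col1a1 11.6-fold (11.3 to 11.9), though its TPM as deposited was 280 in control and 284 in Osr2 cells. Ccn2 (Ctgf, chromosome 10, 24595442 to 24598683), a classic TGF-β target, differed by 6.09.

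TGF-β/Smad3 targets were higher in 23, lower in 5 and neither in 9 of 37, with a median of 1.65, above all random lists (−1.47 as deposited). Smad7, the inhibitory Smad, differed by 4.53, while Postn, with 3 reads in Osr2 cells, was 26.3-fold lower (8.97 to 128), Plod2 differed by −3.26 and Loxl2 by −2.49. Matrix genes were higher in 21 and lower in 5 of 40 (median 1.09, or 1.19 with the members at 0 reads set to 3 reads, and −1.24 as deposited), with Col8a1 at 3.63, Col5a1 at 3.59 and Bgn at −1.99. Mesenchymal genes were higher in 9, lower in 4 and neither in 12 of 25, with a median of 0.69 inside the percentiles (percentile 95.1) and −2.35 as deposited, a scale on which it stood apart with a pseudocount of 5 or the mean over members. Cald1 differed by 3.27 (−0.18 as deposited) and Twist1, an EMT transcription factor, by 2.83 (−0.61), and S100a4 had 0 reads against 117 in control cells. Contractile genes were higher in 11 and lower in 0 of 17 (median 1.81, −0.54 as deposited), and fibroblast markers higher in 6 and lower in 4 of 23 (percentile 51.4), but in 0 and 16 as deposited (median −1.83).

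Immediate early genes were higher in 16 of 17 and lower in 0 (median 2.41, −0.74 as deposited), with Junb at 3.34 (−0.15), Ier2 at 3.31 (−0.18) and Zfp36 at 3.24 (−0.14). BMP pathway genes were higher in 12 and lower in 2 of 19 (median 1.53, −0.65 as deposited), with Smad6 at 4.71, the BMP antagonist Nog at 4.70 and Id3 at 3.91, and Id2 at 0 reads against 243 in control cells. Wnt ligands, receptors and inhibitors were higher in 17 and lower in 4 of 32 (median 1.05), but in 1 and 22 as deposited (median −1.37). Canonical Wnt targets were higher in 10, lower in 2 and neither in 14 of 26 (median 0.69, percentile 99.0, −1.72 as deposited), with Dkk2 at 4.40 and Fst, an activin antagonist, at 4.21. Inflammatory cytokines were higher in 10 and lower in 1 of 17 (median 1.27, −1.13 as deposited), with Cxcl2 at 4.02 and Ccl2 at −2.85. All 8 mitochondrially encoded genes were higher (median 5.04, 1.53 as deposited), with ND5 at 5.64.

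Pluripotency genes were higher in 5, lower in 6 and neither in 13 of 24 (4 and 3 after read subtraction), with a median of 0.19 inside the percentiles (percentile 93.6) and −2.04 as deposited. Klf2 differed by 4.79, Klf5 by 2.78 (−0.57 as deposited), Tdh by −1.51 and Nr0b1 by 0.20 (−3.18). Epithelial genes were higher in 3, lower in 5 (2 after read subtraction) and neither in 11 of 19 (median −0.23, percentile 83.5, and 0.02 with the 5 members at 0 reads set to 3 reads). Cell-cycle genes were lower in 13 and higher in 3 of 38 (median −0.67), with Pcna, the sliding clamp of DNA replication, at −4.04. Of 31 nuclear genes of oxidative phosphorylation, 16 were lower and 0 higher (median −1.06), with Atp5c1 at −3.04. Of 25 cholesterol synthesis genes 11 were lower and 1 higher (median −0.85), and of 25 glycolysis and hypoxia genes 11 were lower and 1 higher (median −0.73). Ribosomal protein genes were lower in 9 and higher in 2 of 36 (median −0.47), with Rps4x at −4.31. Psma6, a proteasome subunit, and Atox1, a copper chaperone, had 0 reads, against 1049 and 493 in control cells.

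In all, 2687 genes were higher and 3768 lower, against 47 higher and 11900 lower on TPM as deposited and 2388 and 3013 after read subtraction. Of 39 lists 19 stood apart, all 19 of them on each of the 3 scales, but 22 medians had the opposite sign as deposited, where no list had more than 5 higher members. Read subtraction leaves both treated columns as they are apart from the scaling, so that scale is no separate check in this comparison. Across genes, the Osr2 differences without and with SB431542 had a Pearson r of 0.42 (Spearman 0.42), or 0.51 (0.51) on TPM as deposited, but r was −0.08 (−0.10) after read subtraction. At mean TPM of at least 5 the relative r was 0.415 with a covariance of 0.726, and simulated libraries with shared reads and no difference but counting error gave r of 0.390 with a covariance of 0.0145.

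The third comparison asks what differed with the TGF-β receptor inhibitor in control cells. Among the genes lower with SB431542, Col3a1 differed by −1.45, Ccn2 by −1.41, Col1a1 by −1.36 and Lox by −1.22. After read subtraction these genes were 7.91-fold lower (Col3a1, counting interval 7.68 to 8.14), 7.14-fold lower (Col1a1, 7.01 to 7.28) and 7.17-fold lower (Lox, 6.23 to 8.27). Since no entry had fewer untreated than treated reads, the ratio of treated to untreated TPM could not exceed 1.84-fold (0.88 in log2), so no gene could be called higher before subtraction. The counts were 0 higher and 78 lower, 0 and 46 on TPM as deposited, and 961 and 737 after read subtraction.

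TGF-β/Smad3 targets were lower in 5 and higher in 0 of 37, with a median of −0.35, below all random lists (0.05 as deposited). After subtraction their median was −0.92, with 17 lower and 2 higher. Matrix genes were lower in 5 of 40 (median −0.36, 0.02 as deposited), and after subtraction in 20 with 0 higher (median −1.01), among them Col1a2 at −2.61. Relative medians in the same direction were seen for contractile genes (median −0.33, with 0.05 as deposited and −0.92 after subtraction), immediate early genes (−0.32, 0.08 and −0.96) and BMP pathway genes (−0.39, −0.07 and −0.87), with Id3 at −1.27 and −2.68 after subtraction. Few of their members passed the size rule, with 0 of 17, 0 of 17 and 1 of 19 lower and 0 higher. After subtraction 7, 8 and 8 were lower, and 0, 0 and 1 higher. Mesenchymal genes had a median of −0.15 (percentile 0.19, 0.26 as deposited, −0.45 after subtraction), with Twist1 at −0.62, Sparc at −0.56 and Pdgfra at −0.56. Canonical Wnt targets had a median of −0.08 (percentile 1.58, 0.28 as deposited, percentile 2.49 and so borderline after subtraction), with Fst at −1.12 and Dkk2 at −1.04. Mitochondrially encoded genes were lower in 7 of 8 (median −1.28), but in 0 as deposited (median −0.82) and in 8 after subtraction (median −2.72).

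Epithelial genes, with 0 of 19 higher or lower, had a median of −0.05 (percentile 1.25, but 0.29 at percentile 7.24 as deposited), and pluripotency genes a median of −0.03 (percentile 11.2, 0.36 as deposited) with 1 of 24 lower, Klf2 at −1.34. Cell-cycle genes had a median of 0.09 (percentile 99.95) and 0.40 after subtraction, with the replication genes Ccne2 at 1.73 and Pcna at 1.45 on that scale. Oxidative phosphorylation genes had a median of 0.11, above all random lists, and 0.51 after subtraction. The lowest genes were small RNAs, of which Mir6236 (chromosome 9, 110281287 to 110281409) differed by −3.60. The 5 highest, LOC115487050, LOC115489055, Snord85, Rnu73b and LOC115487522, each differed by 0.39 with equal reads in the 2 columns. Differences in this comparison went with the GC content of the genes, with a Spearman correlation of −0.51 over 12552 genes. In the other comparisons it was 0.17 for Osr2 without SB431542 (−0.13 after read subtraction), 0.31 with it and 0.14 for SB431542 in Osr2 cells. Random lists matched on GC content were drawn only for Osr2 without SB431542. For SB431542 in control cells they were matched on expression alone, so GC content was not tested as a cause of these list medians. Of 39 lists 21 stood apart for SB431542 in control cells, 19 of them on all 3 scales, while 26 medians had the opposite sign as deposited.

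The fourth comparison asks the same in Osr2 cells. Matrix genes were lower with SB431542. Postn (chromosome 3, 54359267 to 54391041) had 3 reads with the inhibitor and was 729-fold lower (249 to 3535). Bgn, a matrix proteoglycan, stood at 312 TPM without and 0.550 TPM with SB431542, 126-fold lower (82.1 to 203). Eln was 38.1-fold lower (29.0 to 51.2), and Mfap4 (chromosome 11, 61485431 to 61488708) had 0 reads against 1626 without the inhibitor. The medians of the pluripotency and epithelial lists were above 0 relative to the median gene. The highest genes were Pcsk1n (chromosome X, 7919822 to 7924410) at 3.40, Mir132 at 3.37, Egr4 at 3.35, ND3 at 3.34 and Ptx3 at 3.32. Of the untreated reads of Pcsk1n 1898 of 1902 matched the treated number, and in TPM as deposited the ratio of treated to untreated could not exceed 2.24-fold. The shared reads cap the relative values as well. These highest genes lie near that cap, so a larger difference could not have been seen.

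Matrix genes were lower in 32 of 40, higher in 1 and neither in 7 (median −2.84, or −2.44 with members at 0 reads set to 3 reads), with Fbln2 at −4.15 and Col3a1 at −3.54. TGF-β/Smad3 targets were lower in 24, higher in 3 and neither in 10 of 37 (median −1.54, below all random lists). Mesenchymal genes were lower in 16, higher in 0 and neither in 9 of 25 (median −1.41), with Fbn1, the microfibril protein, at −3.31 and Mmp2 at −3.24. Fibroblast markers were lower in 17 and higher in 0 of 23 (median −2.42), with decorin (Dcn) at −4.45 and Ly6a (Sca1) at −3.98. Contractile genes were lower in 8 and higher in 1 of 17, with a median of −0.42 inside the percentiles (but percentile 0.88 as deposited), and Acta2 at −3.23. Canonical Wnt targets were lower in 7, higher in 6 and neither in 13 of 26 (median −0.06, percentile 55.7, and 0.13 with members at 0 reads set to 3 reads), with Ccn4 at −4.17 and Nkd2 at 2.42.

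Pluripotency genes were higher in 13, lower in 1 and neither in 10 of 24, with a median of 1.11, above all random lists (−0.05 as deposited). The list includes Klf4, Pou5f1 and Sox2, which the vector carries. The vector's 4 factors were higher in 3 and lower in 0, with a median of 1.08 (−1.17 as deposited, 1.32 after read subtraction). Nr0b1 differed by 3.25, L1td1 by 2.76, Klf5 by 2.48 and Mybl2 by 2.35. The reads of Nr0b1 in the untreated column equalled those in the treated one. If they are shared, Nr0b1 was at least 355-fold higher after subtraction, a bound that covers counting error only. Epithelial genes were higher in 9, lower in 3 and neither in 7 of 19 (median 0.74, or 1.12 with the 5 members at 0 reads set to 3 reads, and −0.09 as deposited), with Crb3, an apical polarity protein, at 2.12, and Cdh3, with 1 read, 158-fold lower (28.3 to 6236). Cell-cycle genes were higher in 14 and lower in 3 of 38 (median 0.70, −1.16 as deposited), with Kif11, a spindle motor, at 2.42 and Pcna at −2.15. Histone genes were higher in 12 and lower in 1 of 21 (median 1.11, −0.95 as deposited), with H1f1 at 2.55. Trophoblast genes were higher in 4 and lower in 1 of 6 (median 1.65, −0.03 as deposited), with Esx1 at 3.29 and Hand1 at 2.42.

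Inflammatory cytokines were higher in 10 and lower in 4 of 17 (median 1.10, −0.35 as deposited), with Cxcl2 at 3.29 and the acute phase gene Saa3 at 3.11. Immediate early genes were higher in 8 and lower in 2 of 17 (median 0.92, but −1.25 as deposited, inside the percentiles), with Atf3 at 1.94 (−0.20), Junb at 1.76 (−0.48) and Fosb at −2.62. All 8 mitochondrially encoded genes were higher (median 3.04, 0.79 as deposited, 5.14 after read subtraction). Unfolded protein response genes were lower in 10 and higher in 2 of 24 (median −0.84), cholesterol synthesis genes lower in 14 and higher in 0 of 25 (median −1.05), with Cyp51 at −2.38, and oxidative phosphorylation genes lower in 11 and higher in 0 of 31 (median −0.70). In all, 2224 genes were higher and 3601 lower, against 16 higher and 8665 lower on TPM as deposited and 2442 and 3051 after read subtraction. Of 39 lists 19 stood apart, 16 of them on all 3 scales, while 13 medians had the opposite sign as deposited, where no list had more than 3 higher members. Osr2 differed by 0.14 (−2.03 as deposited).

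**Figure D3:**
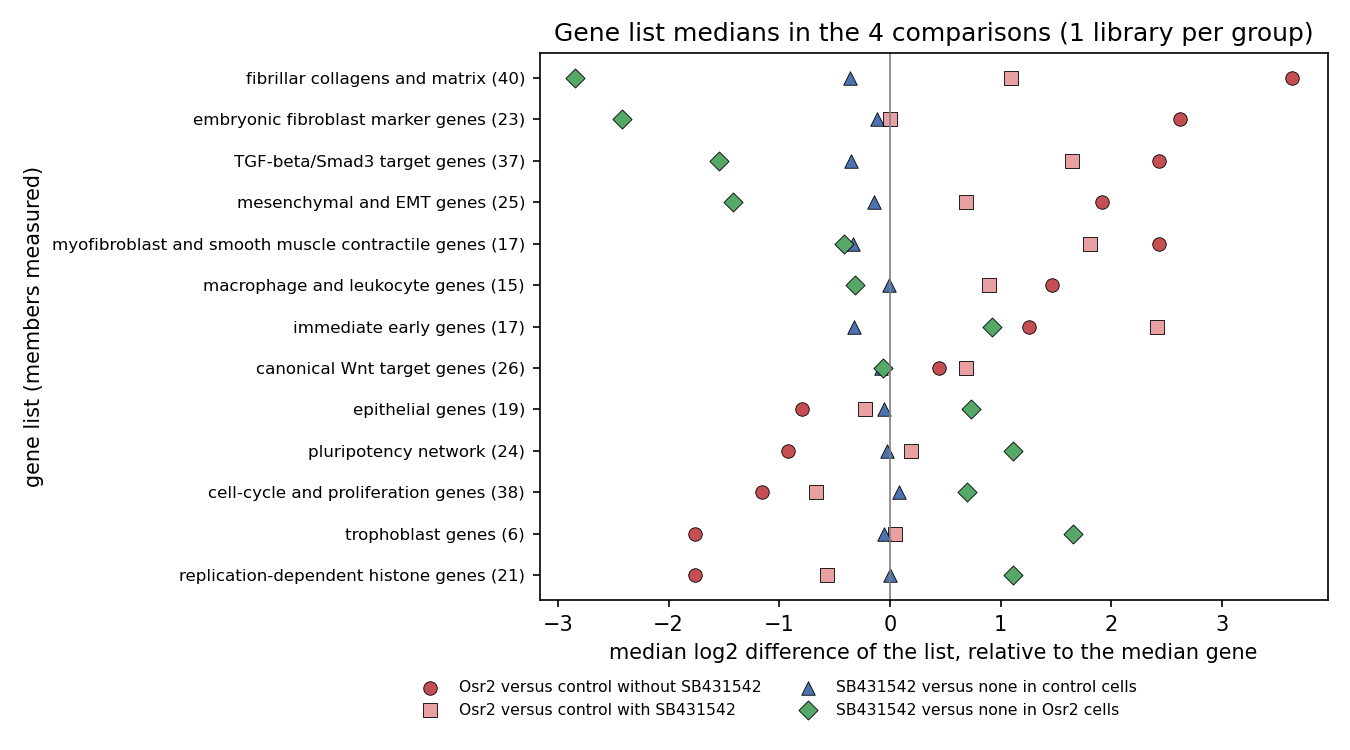
Median log2 difference relative to the median gene (x axis) of 13 gene lists (y axis, with the number of measured members) in the 4 comparisons, 1 library per group. Matrix genes have medians of 3.63 and 1.09 for Osr2 against control without and with SB431542, and of −0.36 and −2.84 for SB431542 in control and in Osr2 cells. Shared reads keep the differences for SB431542 in control cells small. After read subtraction the medians for SB431542 are −1.01 in control and −2.56 in Osr2 cells.

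The SB431542 difference in Osr2 cells less that in control cells was below 0 for many matrix genes, with Bgn at −6.54. Matrix genes were lower by this measure in 29 of 40 and higher in 3 (median −2.28), but in 23 and 8 after read subtraction (median −1.85). TGF-β/Smad3 targets were lower in 21 and higher in 4 of 37 (median −1.26), but in 16 and 10 after read subtraction (median −0.65), and mesenchymal genes lower in 16 and higher in 2 of 25 (median −1.48), but in 12 and 4 (median −0.98). Pluripotency genes were higher in 14 and lower in 1 of 24 (median 1.20, −0.37 as deposited, 0.81 after read subtraction), with Nr0b1 at 3.25 and L1td1 at 2.84, and epithelial genes higher in 8 and lower in 3 of 19 (median 0.57, −0.43 as deposited, 0.37 after read subtraction). The vector's 4 factors were higher by this measure in 3 and lower in 0 (median 1.07, −1.64 as deposited, 1.23 after read subtraction). Canonical Wnt targets had a median of 0.26 inside the percentiles (percentile 89.4), with −1.58 as deposited. Of 39 lists 18 stood apart by this measure, 17 of them on all 3 scales, while 17 medians had the opposite sign as deposited and 7 after read subtraction. The highest genes were ND4 (4.67), Mir7082 (4.62) and Mir132 (4.51), and 2444 genes were higher and 3739 lower, against 40 and 10177 on TPM as deposited and 2974 and 4150 after read subtraction. Across genes, the SB431542 differences in control and in Osr2 cells had a Pearson r of −0.20 (Spearman −0.32), −0.10 (−0.20) on TPM as deposited and −0.30 (−0.33) after read subtraction.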

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

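The counts of entries with fewer reads in an untreated column, of entries outside a random share and of genes at 0 reads, the comparison of TPM totals, the read subtraction and the comparison with the vector's factors are tests that were chosen only after the result was seen.

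Among the 5 primary lists, 3 differences between groups stood out because the medians of a list lay in opposite directions in the groups compared, and with 1 library per group these differences were not tested. The pluripotency network had a median Osr2 difference of −0.92 without SB431542 and 0.19 with it, 1.12 apart. The same list had a median SB431542 difference of −0.03 in control cells and 1.11 in Osr2 cells, 1.14 apart. Epithelial genes had a median SB431542 difference of −0.05 in control cells and 0.74 in Osr2 cells, 0.79 apart. In control cells the shared reads keep such differences small, as 0% of genes simulated 4-fold apart were found before read subtraction. After it, the SB431542 medians in control and Osr2 cells were −0.06 and 1.06 for pluripotency genes and −0.14 and 0.70 for epithelial genes. Other lists had wider opposite pairs, such as mitochondrially encoded genes at −1.28 and 3.04 for SB431542 in control and Osr2 cells. The opposite directions rest on the median gene, as the pluripotency list had −1.16 and −2.04 for Osr2 as deposited, and for SB431542 the signs as deposited were the reverse, with 0.36 and −0.05 for the pluripotency and 0.29 and −0.09 for the epithelial list. The 3 differences of primary lists use the Osr2 library with SB431542, whose make-up and shared reads are weighed next.

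In reads, the untreated columns never lay below the treated columns, with 0 such entries in both kinds of cell. Separate libraries with independent reads are excluded, as 20 simulated pairs gave at least 1998 such entries. The treated column is no random part of the untreated reads either, since 75.2% of entries in control cells and 79.2% in Osr2 cells lay outside the 95% binomial range of the overall share. The untreated columns may hold the treated libraries' reads in addition to their own, and the values after read subtraction rest on this reading. A treated column made of a non-random part of the untreated reads was not tested, nor was any biological explanation.

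On TPM as deposited most genes were lower in the Osr2 library with SB431542, with higher genes at 0.393% of those past the size rule against the control library with SB431542. Totals that the listed genes do not hold may account for part of this, as a shift of −1.28 of the −3.51 was left with the listed genes at the same TPM total, which cannot be told apart from a difference of the cells. A few abundant listed genes are excluded as the whole cause, as leaving out mitochondrial genes and the 20 entries of most reads would raise the others by 0.78 (log2), while transcripts outside the listed genes were not tested. Lower total depth alone gave a small part of the genes past the size rule after centring, as random thinning of the control library to this depth moved 504 genes, 7.81% of the 6455 seen. The thinning matched total reads but not the make-up of this library. Mitochondrial genes held 15.3% of its reads, against 0.705% in the control library with SB431542, so this share may be too low. A library made from few distinct molecules stays open and was not tested beyond the 183 of 9144 genes at 0 reads, as does a difference of the cells.

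Matrix and TGF-β target genes were higher with Osr2 without SB431542. GC content is excluded as the whole cause, since the TGF-β list's median exceeded that of random lists matched on expression and GC by 2.37, and so are the shared reads, since the median was 1.75 after read subtraction. More fibroblasts without the reprogramming vector could also give such a pattern and cannot be told apart from an effect of Osr2 by these values, though the labels say that reprogrammed cells were selected with 2 µg/mL blasticidin S, which argues against many such cells. The vector's 4 factors had a median of −0.25 (−1.04 as deposited, −0.63 after read subtraction), while the pluripotency list had −0.92 (−1.16 and −1.13). Markers of fibroblasts (19 of 23 higher, median 2.62, with 8 of the 23 also in the matrix or TGF-β lists) go with such cells. Markers of macrophages and leukocytes were higher too (12 of 15, median 1.46, with Lyz2 at 7.97 TPM in control and 24.3 TPM in Osr2 cells). They mark other cells than fibroblasts and so do not speak for this explanation, and a difference in the share of such other cells was not tested. An effect of Osr2 is the biological explanation that the design names, and it stays open as a hypothesis.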

How the results depend on the processing

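The relative values and the read subtraction are tests that were chosen only after the result was seen. The 10 alternatives fixed in advance and these 2 gave 100 counts of genes, of which 37 were within 1.5 times the value on TPM as deposited and 63 were not. Of 16 correlations 12 stayed within 0.1, and all 10 numbers of lists that stand apart stayed within 1.5 times. Of 250 medians of primary lists, taken less the random lists' median, 214 counted as the same. Among these, medians that stood apart did so again in the same direction. The others stayed inside the percentiles and changed by less than the SD of the random lists. A further 23 stayed inside but changed by more, 7 no longer stood apart and 6 newly did. None that stood apart reversed. Part of this agreement is built in. Median-of-ratios scaling, rescaling and centring change a whole library by a single factor, which moves a list and its random lists nearly alike. No paired analysis was possible because each group has 1 library and no label pairs them. For the values below the cause was not tested, except that a stricter or looser size rule or filter changes counts by its construction. Depth was lowest in the Osr2 library with SB431542, with 1631971 reads. A 0 there sets no limit, since 183 of 9144 genes of at least 20 expected reads had 0 reads, against 0 by random thinning, a loss that depth alone does not give.

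Counts are higher and lower genes. In the comparison of Osr2 with control without SB431542 they were 551 and 1812 with a pseudocount of 5, 1840 and 1913 with median-of-ratios scaling, 1777 higher when rescaled without mitochondrial and the top 20 genes, 1657 and 7147 at 1.5-fold, 307 and 642 at 4-fold, 2236 and 1540 centred on the median gene, and 1936 and 1454 after read subtraction. With SB431542 they were 78 higher with a pseudocount of 0.1, 28 higher with 5, 861 and 6837 with median-of-ratios scaling, 1553 and 6434 rescaled, 85 higher at 1.5-fold, 17 higher at 4-fold, 2687 and 3768 centred, and 2388 and 3013 after subtraction. For SB431542 in control cells they were 73 lower with a pseudocount of 0.1, 5 lower with 5, 13 lower at a filter of 5 TPM, 90 lower rescaled, 1711 and 85 at 1.5-fold, 10 lower at 4-fold, 78 lower centred, and 961 and 737 after subtraction. For SB431542 in Osr2 cells they were 42 higher with a pseudocount of 0.1, 5 and 4262 with 5, 653 and 5589 with median-of-ratios scaling, 1809 and 4864 rescaled, 78 higher at 1.5-fold, 0 and 3699 at 4-fold, 2224 and 3601 centred, and 2442 and 3051 after subtraction. For the difference between the SB431542 differences they were 13 and 6222 with a pseudocount of 5, 18 higher at a filter of 5 TPM, 760 and 6107 with median-of-ratios scaling, 1982 and 5016 rescaled, 81 higher at 1.5-fold, 2 and 5558 at 4-fold, 2444 and 3739 centred, and 2974 and 4150 after subtraction.

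The correlation of the Osr2 differences without and with SB431542 reversed to −0.0780 after read subtraction. That of the SB431542 differences in control and Osr2 cells was −0.27 with a pseudocount of 5, −0.52 with no filter and −0.30 after subtraction.

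Primary list medians less those of random lists changed as follows. A pseudocount of 0.1 gave, for epithelial genes, 0.29 for Osr2 with SB431542 and −0.14 for SB431542 in control cells, for pluripotency genes 0.25 for Osr2 with SB431542, and for Wnt targets 0.16 for SB431542 in Osr2 cells and 0.55 for the difference between the SB431542 differences. A pseudocount of 5 gave 0.57 for mesenchymal genes for Osr2 with SB431542, now standing apart, −0.12 for epithelial genes for Osr2 without SB431542, no longer apart, −0.0284 for these in control cells with SB431542, and −0.17 for Wnt targets for the difference. A filter of 5 TPM gave −0.50 for epithelial genes for Osr2 without SB431542, no longer apart, and 0.37 with it, and −0.47 and −0.20 for Wnt targets for SB431542 in Osr2 cells and the difference. With no filter Wnt targets for Osr2 without SB431542 were at 0.28, no longer apart. Median-of-ratios scaling gave −0.10 for epithelial genes for SB431542 in control cells, now apart, and 0.15 for Wnt targets in Osr2 cells. Rescaling gave 0.58 for epithelial and 0.55 for pluripotency genes for Osr2 with SB431542, and −0.13 for epithelial genes for SB431542 in control cells, now apart.

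The mean over members gave 0.49 for mesenchymal genes for Osr2 with SB431542, now apart, −0.36 for epithelial genes for Osr2 without SB431542, no longer apart, and −0.11 for Wnt targets for the difference. Members of at least 5 TPM gave −0.0020 for epithelial genes for SB431542 in control cells, and −0.51 and −0.22 for Wnt targets for SB431542 in Osr2 cells and the difference. Centring gave, for Osr2 with SB431542, 0.51 for epithelial and 0.51 for pluripotency genes, −0.11 for epithelial genes for SB431542 in control cells, now apart, and 0.43 for Wnt targets for Osr2 without SB431542, no longer apart. The last was at the 98.4th percentile among 10000 lists matched on TPM as deposited, so this call is borderline. Read subtraction gave 0.28 for epithelial and 0.41 for pluripotency genes for Osr2 with SB431542, −0.36, now apart, and −0.16 for these lists for SB431542 in control cells, and for Wnt targets 0.30 for Osr2 without SB431542 and −0.25 for SB431542 in control cells, both no longer apart, and 0.48 for the difference.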

Other observations

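The look at imprinted genes, the relative values and the read subtraction are tests that were chosen only after the result was seen, while the test on further imprinted genes was written before those genes were looked at. Imprinted genes of the fetal growth network were among those higher with Osr2 without SB431542, and the ones named in this paragraph were picked because their values had been seen. The long noncoding RNA H19 stood at 115 TPM in control and 1642 TPM in Osr2 cells (4.62 in log2 relative to the median gene). The cell-cycle inhibitor Cdkn1c (p57) differed by 4.99, Igf2 by 3.59, Dlk1 by 3.10 and Meg3 by 3.09, while Peg10 differed by −3.17. With SB431542 in Osr2 cells H19 differed by −3.04, Cdkn1c by −3.42, Meg3 by −2.65 and Igf2 by −2.63. In that comparison Dlk1 differed by −0.05 and Peg10 by 2.03.

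A wider description, offered as a hypothesis, is a higher level of the imprinted gene network with Osr2. It names no cause, and its test asks only whether further imprinted genes were higher in the same libraries. Of 22 further imprinted genes 18 were measured, of which 9 were higher, 2 lower and 7 neither. Their median was 1.03, at the 99.97th percentile of matched random lists, and 1.06 after read subtraction. Plagl1, a transcription factor of this network, differed by 3.75, Slc22a18 by 2.47 and Igf2r by 2.05, while Snrpn differed by −1.68 and Nnat by −1.16. The same 18 genes had medians of −0.27 for Osr2 with SB431542 (percentile 34.6), 0.05 for SB431542 in control cells (82.6) and −1.05 for SB431542 in Osr2 cells (0.67). The prediction was met, but these genes include fibroblast genes, and 1 library per group shows no more than this.

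Among other lists, for Osr2 without SB431542, Hox genes were higher in 8, lower in 1 and neither in 19 of 28 (median 0.67, percentile 99.9, −0.01 on TPM as deposited), but after read subtraction 6 were higher and 2 lower with a median of 0.31 inside the percentiles (percentile 87.6), with Hoxc8 at 2.73 and Hoxb8 at 2.33. Medians lay inside the percentiles for chondrogenic and tendon genes (5 higher and 2 lower of 11, with Fmod at 3.69 and Sox6 at −1.47), osteogenic genes (0 higher and 2 lower of 7, with Alpl at −2.52), adipogenic genes (3 higher and 0 lower of 11, median 0.47, −0.04 as deposited, with Cebpa at 2.12), skeletal muscle genes (3 higher and 1 lower of 4), keratinocyte genes (1 higher and 2 lower of 10), endothelial genes (2 higher and 0 lower of 8, median 0.17, −0.30 as deposited, with Flt1 at 2.19) and endoderm genes (3 higher and 1 lower of 6, with Pdgfra at 3.35 and Lama1 at −3.44). After read subtraction the medians of the chondrogenic and tendon (−0.50) and keratinocyte genes (−0.52) stood apart. Medians also lay inside the percentiles for mesoderm (0 higher and 1 lower of 3), germline (0 and 0 of 3) and erythroid genes (0 and 1 of 2), except mesoderm after read subtraction (percentile 2.475). p53 targets were higher in 6 and lower in 0 of 26 (median 0.41, percentile 95.9, but −0.30 at percentile 97.6 on TPM as deposited), and ribosomal protein genes higher or lower in 0 of 36 (median 0.08, percentile 37.5, −0.72 on TPM as deposited).

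Of 3 metabolic lists, 1 stood apart for Osr2 without SB431542. Glycolysis and hypoxia genes were higher in 4 and lower in 4 of 25 (median −0.27), but in 2 and 12 as deposited (median −0.94), with Hk2, a hexokinase, at −1.59 and Adm at 2.42. Cholesterol synthesis genes were higher in 3 and lower in 1 of 25 (median 0.32, −0.41 on TPM as deposited), but in 9 and 1 after read subtraction. Nuclear genes of oxidative phosphorylation were higher or lower in 0 of 31, though lower in 17 as deposited, with a median of −0.30 that stood apart (percentile 1.92) but was 0.06 after read subtraction.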
